A study of Saccharomyces cerevisiae with 3 samples.

How the data were processed

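The series holds 3 arrays of Saccharomyces cerevisiae, the budding yeast, from a screen for genetic interactions of CIN8. Per the labels' protocols, a pool of 5896 heterozygous diploid deletion strains, each carrying 2 short DNA tags that identify it, received a cassette that replaced CIN8 with URA3. The pool was sporulated, and haploids were selected on plates with 5-fluoroorotic acid (5-FOA), which kills cells that express URA3, and on plates without uracil, where cells with URA3 grow. The first plates gave a pool of single mutants and the second a pool of double mutants, both harvested after 2 days at 30 °C. The tags were amplified from genomic DNA, although the sample records give total RNA as the molecule. Tags of the single-mutant pool were labelled with Cy5 and those of the double-mutant pool with Cy3, on all 3 arrays, and the images were read with GenePix 5.1, per the labels. Experiments 1, 2 and 3 used 0.1, 0.15 and 0.2% 5-FOA. The labels do not say whether the experiments came from separate transformations or sporulations, so that p-values measure only the spread between these 3 arrays, which may be technical.

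The authors deposited log2 ratios, 1 value per probe and array. The formula, the normalization, the filters and the direction of the ratio were not given in the sources used here. Raised to the power of 2, all values were multiples of 0.01 within a relative tolerance of 0.001. The medians of the deposited log2 ratios were -0.17, -0.15 and -0.15 in experiments 1, 2 and 3, so that the columns were not centred on 0. Of 22575 probes, 19061, 18788 and 19016 had a value. A set of 36 values stood at a ratio of 999999, against 1692 for the next highest, and was treated as placeholders and left out, a choice made after the values were seen. The lowest ratio, 0.01, occurred 210 times and was kept. The files used here hold no intensities, so that signal over background is unknown, and the number of arrays limits the precision.

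The platform annotation gave 1 gene symbol for 18794 probes, several for 0 and none for 3781. The named probes covered 5325 genes, of which 5321 matched the RefSeq table of assembly R64. Named probes fell into a pair of blocks. In all 9397 pairs, a probe and the probe 10971 identifiers later named the same gene. The blocks were treated as the 2 tags of each strain and are called tag set A and tag set B, since the sources used here do not say which holds the upstream tags. A total of 4439 genes had 2 probes and 781 had 12. The median SD was 0.13 among repeated spots of 1 tag (1586 tags) and 0.32 between the 2 tags of the same strains (793 strains).

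Values were centred on the median of each array and tag set. Spots were averaged per tag and tags per strain. Strains with a value on all 3 arrays were tested with limma 3.58.1 in R 4.3.3, with lmFit on an intercept and eBayes. The mean log2 ratio was tested against 0, two-sided, with Benjamini-Hochberg adjustment, and strains under 0.05 were called. The same test was run on each tag set alone. The lists of genes were fixed from textbook knowledge before the data were examined. They were spindle motors and midzone, dynein and dynactin, spindle checkpoint, prefoldin, tubulin and cofactors, sister chromatid cohesion, Ctf19 kinetochore, SWR1 and H2A.Z, uracil biosynthesis, uracil uptake, salvage and regulation, vacuolar ATPase, mitochondrial ribosome, recombinational repair, and essential genes, with CIN8 alone as the query. The 14 lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. The version with an estimated correlation rests on 2 residual degrees of freedom here and has little power. A high p-value from it thus does not show that a list lacks a shift. The estimated correlations ran from -0.24 (uracil biosynthesis) to 0.17 (Ctf19 kinetochore). A trend over the 5-FOA percentage was fitted with 1 residual degree of freedom. Strains of open reading frames (ORFs) on the left arm of chromosome V were placed by the numbers in their systematic names, and medians were set against 10000 random sets of the same size. Pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 in Python 3.11.15 served for tables and plots.

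The rule for named strains took CIN8 and KIP1, the 15 called strains with the largest positive mean and the 5 with the largest negative mean, given the same sign on all arrays and in both tags where measured, up to 4 called members per list, and up to 3 strains per direction of the trend. Further list members, named where their tags disagreed or where a count left few, and the strains next to CIN8 were chosen after their values were seen. The rule spoke of a depletion side, which was taken as the positive side. By a rule fixed before the data were examined, the sign was to be read as a direction only if CIN8 and the uracil biosynthesis list lay on the same side of 0. They did not, and no direction is given in the results.

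The test was tested on simulated data with normal noise, with variances drawn from the distribution that limma fitted to these arrays, over 5204 strains, as means of 20 runs. With 1800 strains changed, a number chosen near the observed count of calls, 31.5% of those changed by 0.5 on the log2 scale were called, 73.8% of those by 1, 90.7% of those by 2 and 96.8% of those by 4, and 3.27% of calls were false. With 200 changed, the shares were 0.1%, 15.6%, 67.6% and 87.0%, and 4.22% of calls were false. Noise of the same shape as the model assumes makes this a favourable case. Unchanged strains were set at exactly 0, so that the false shares do not cover unchanged strains whose tags lie off 0. The essential genes, set as a background, had a median of -1.07 in the data. For the gene lists, camera gave an unadjusted p under 0.05 for 49 of 50 simulated lists of 10 strains shifted by 2, and for 1 of 50 that were not shifted. Alternatives covered the centring, scaling between arrays, the use of the tags, the number of arrays required, robust eBayes, 5-FOA as a covariate, each array left out, the placeholders, the lowest ratios and the median of spots.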

Results

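The arrays measured, for each deletion strain, the abundance of its tags in a pool of haploid single mutants against a pool of haploid double mutants that also lacked CIN8, the gene of a mitotic kinesin motor that slides spindle microtubules apart. A total of 3 experiments were compared, each with both pools on 1 array, and values are mean log2 ratios ± SD over the 3 arrays after centring. The question was which deletions change the share of a strain among cells that lack CIN8. The sign is that of the deposited ratio. The side of the uracil biosynthesis strains is called positive, and no pool is assigned to either side. Between pairs of arrays, Pearson's r across the named probes was 0.70 to 0.73 and Spearman's rho 0.74 to 0.76. Probes are not independent replicates.

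Strains of the spindle motor, checkpoint, dynactin, prefoldin and cohesion lists stood among the largest positive ratios, beside strains of other processes. KIP1 encodes the other kinesin of the CIN8 family in yeast, and its deletion strain had a ratio of 4.99 ± 0.50 (SD, n = 3), or 31.7-fold, with 5.16 in tag set A and 4.82 in tag set B (limma, adjusted p = 0.0090). MAD3, of the spindle checkpoint, stood 34.4-fold from 0, with tags at 7.29 and 2.92. JNM1, of dynactin, stood at 3.54 ± 0.44, PFD1, of the prefoldin chaperone, at 3.80 ± 0.23, and CTF18, of a cohesion clamp loader, at 3.44 ± 0.09. The query strain, CIN8, lay on the other side at -2.23 ± 0.26, with -2.16 and -2.30 in its tags (adjusted p = 0.0106).

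Of 5204 strains tested, limma called 1748, of which 842 were positive and 906 negative. A total of 771 were also at least 2-fold from 0, with 278 positive and 493 negative. The balance of the sides depended on the centring, and without it 602 were positive and 1261 negative, or 217 and 680 at 2-fold or more. No strain was called when any 1 of experiments 1, 2 or 3 was left out (0 calls each; 1876, 1993 and 1874 strains had an unadjusted p under 0.05). With the 5-FOA percentage as a covariate 228 strains were called, and 595 with the lower of the 2 tag values.

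The other strains among the 15 largest positive ratios came from several processes. AAT2, encoding an aspartate aminotransferase, stood at 5.39 ± 0.30, ARD1, the catalytic subunit of an N-terminal acetyltransferase, at 4.24 ± 0.32, and SGO1, the shugoshin of centromeric cohesion, at 3.97 ± 0.75. BUB2, of the mitotic exit checkpoint, stood at 3.40 ± 0.26. ENP1, an essential gene of ribosome assembly that was not on the list of essential genes, stood at 5.63 ± 0.60 with 2 values missing. HOT1, a transcription factor of the osmotic stress response, stood at 3.88 ± 0.09, but its tags gave 7.18 and 0.57. NPR2, next to CIN8 on chromosome V, stood at 3.56 ± 0.51. Of these 15 strains, 13 were called by both tags.

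The 5 strains with the lowest means were limited by the lowest deposited ratio, 0.01, so that their means are upper bounds, their SDs are not measures of error and their order is not known. CPA1, a subunit of carbamoyl phosphate synthetase, stood at -6.31 or below, with 4 of 5 values at the lowest ratio. FUR4, the uracil permease, stood at -6.10 or below (12 of 21 values). YOR302W, the upstream reading frame of CPA1, stood at -5.56 or below (3 of 6), LAS1 at -5.30 or below (3 of 6) and TDA9 at -5.14 or below (1 of 3). LAS1 alone of these 5 was called by both tags. CPA1, FUR4, YOR302W and TDA9 had 7, 15, 6 and 3 empty values, so that not both of their tags could be tested.

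The tags of a strain have different sequences, and their calls were compared. Both tags were called in the same direction in 724 of the 4293 strains measured by both, 479 positive and 245 negative. Independent tags would give 162 and 93.7. A further 63 strains were called by both tags in opposite directions. Across these 4293 strains, which are not independent replicates, Pearson's r between the tags was 0.48 and Spearman's rho 0.56. Among the called strains with both tags (1531), r was 0.62, but calls rest on the mean of the 2 tags, which can itself raise r. No strain was called by both tags without experiment 1 or experiment 3 (0 each), and 2 were without experiment 2.

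**Figure D1:**
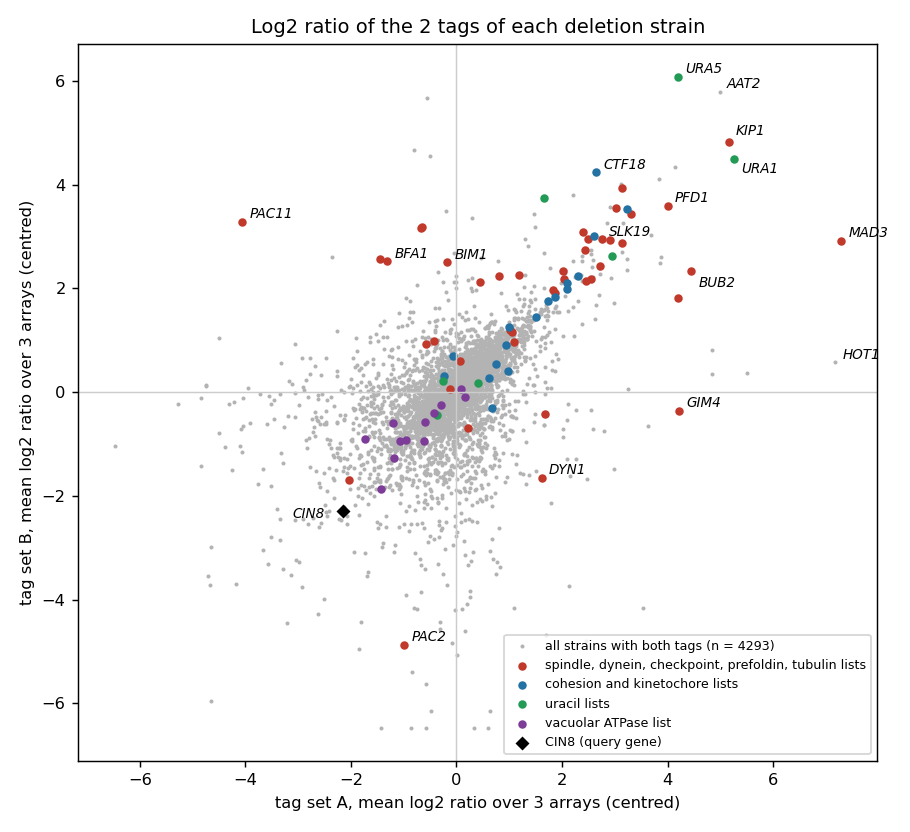
Mean log2 ratio over 3 arrays in tag set A (horizontal axis) against tag set B (vertical axis), with 1 point per strain (4293 strains) and colours for gene lists. KIP1 lies at 5.16 and 4.82 and CIN8 at -2.16 and -2.30, while PAC11 (-4.06 and 3.28), DYN1 (1.61 and -1.65) and GIM4 (4.21 and -0.36) have tags of opposite sign.

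All measured checkpoint strains and most dynein strains were positive. All 7 measured members of the spindle checkpoint list were called positive, with a median of 2.74, and 6 of them by both tags. The other, BFA1 (0.61 ± 0.20), was called negative in tag set A (-1.31) and positive in tag set B (2.52). MAD3, BUB2, MAD1 (2.93 ± 0.20) and MAD2 (2.74 ± 0.19) led the list. The dynein and dynactin list covers the motor that pulls the spindle into the bud neck and factors that work with it. Of its 11 measured strains, 9 were positive, 8 of them by both tags, with a median of 2.36. The 9 included NUM1 (3.36 ± 0.18), NIP100 (3.29 ± 0.19) and LDB18 (tags 3.13 and 2.87). PAC1 (1.25 ± 0.47) was among the 9, with tags at -0.67 and 3.16. DYN1 and PAC11 were not called. Their tags gave 1.61 and -1.65 for DYN1, and -4.06 and 3.28 for PAC11. The counts adjusted over the list alone were the same, 7 and 9. Camera gave an adjusted p of 2.1e-05 for the checkpoint list and 2.8e-05 for the dynein list. Each had an adjusted p = 0.136 with an estimated correlation, which was 0.0016 for the checkpoint list and -0.072 for the dynein list.

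Spindle motor and midzone strains were positive in 7 of 12 cases, 5 of them by both tags, with a median of 1.09, or in 10 of 12 adjusted over the list alone. After KIP1 came SLK19 (2.85 ± 0.06), ASE1 (2.17 ± 0.22), which bundles midzone microtubules, and KAR3 (1.89 ± 0.41), a motor of opposite polarity. BIM1, a microtubule plus-end protein, was called at 1.16 ± 0.37 with tags at -0.18 and 2.50. Of the 6 prefoldin strains, which lack a chaperone that delivers tubulin and actin, 5 were positive, 3 of them by both tags, with a median of 1.82, and 5 adjusted over the list alone. GIM5 stood at 2.58 ± 0.26 and YKE2 at 1.72 ± 0.04. GIM4 stood at 1.93 ± 0.15, with tags at 4.21 and -0.36, and PAC10 (1.26 ± 0.30) was called negative in tag set A (-0.66) and positive in tag set B (3.18). The motor and prefoldin lists each had a camera adjusted p of 1.2e-04, and for both the adjusted p = 0.136 with an estimated correlation. The prefoldin list had an adjusted p of 0.0715 in tag set A alone.

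Tubulin and tubulin cofactor strains went both ways. CIN1 (2.72 ± 0.23) and CIN2 (1.88 ± 0.19), which act on beta-tubulin folding, and CIN4 and TUB3 were the 4 positive members of 7, all by both tags. ALF1 (-1.86 ± 0.41) and PAC2 (-2.93 ± 0.69), which act on alpha-tubulin, were the 2 negative members, ALF1 alone by both tags, and PAC2 had 12 empty values and 3 of 24 at the lowest ratio. RBL2 (0.17 ± 0.29, tags -0.58 and 0.92) was not called. A split between alpha- and beta-tubulin was not tested. The counts adjusted over the list alone were also 4 and 2. The median was 1.10 and camera's adjusted p was 0.095 (adjusted p = 0.250 with an estimated correlation). Without centring the adjusted p was 0.0377.

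Cohesion and kinetochore strains were positive in most cases, but not all. Of the 9 sister chromatid cohesion strains 7 were positive, all 7 by both tags, with a median of 2.04, and 7 adjusted over the list alone. CTF18, CTF8 (3.38 ± 0.19) and DCC1 (2.80 ± 0.31) encode parts of 1 clamp loader, and TOF1 (2.27 ± 0.21) is a replication fork protein. Of the 10 Ctf19 kinetochore strains 6 were positive, 5 of them by both tags, with a median of 0.67, and 8 adjusted over the list alone. NKP2 (2.10 ± 0.21), CTF19 (1.74 ± 0.10), MCM22 (1.12 ± 0.05) and CHL4 (0.93 ± 0.29) led them. The cohesion and kinetochore lists had camera adjusted p-values of 2.1e-05 and 1.2e-04, with an adjusted p = 0.136 and an adjusted p = 0.152 with an estimated correlation.

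Strains lacking the SWR1 complex, which places the histone variant H2A.Z, were positive in 6 of 10 cases, 4 of them by both tags, with a median of 1.09, and in 6 adjusted over the list alone. SWR1 stood at 1.64 ± 0.20, HTZ1, which encodes the variant, at 1.57 ± 0.24, ARP6 at 1.27 ± 0.02 and SWC5 at 1.22 ± 0.26. BDF1 was called at 0.60 ± 0.10, with tags at 1.63 and -0.43. The SWR1 list had a camera adjusted p of 0.0012, with an adjusted p = 0.143 with an estimated correlation and 0.0601 in tag set B alone.

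**Figure D2:**
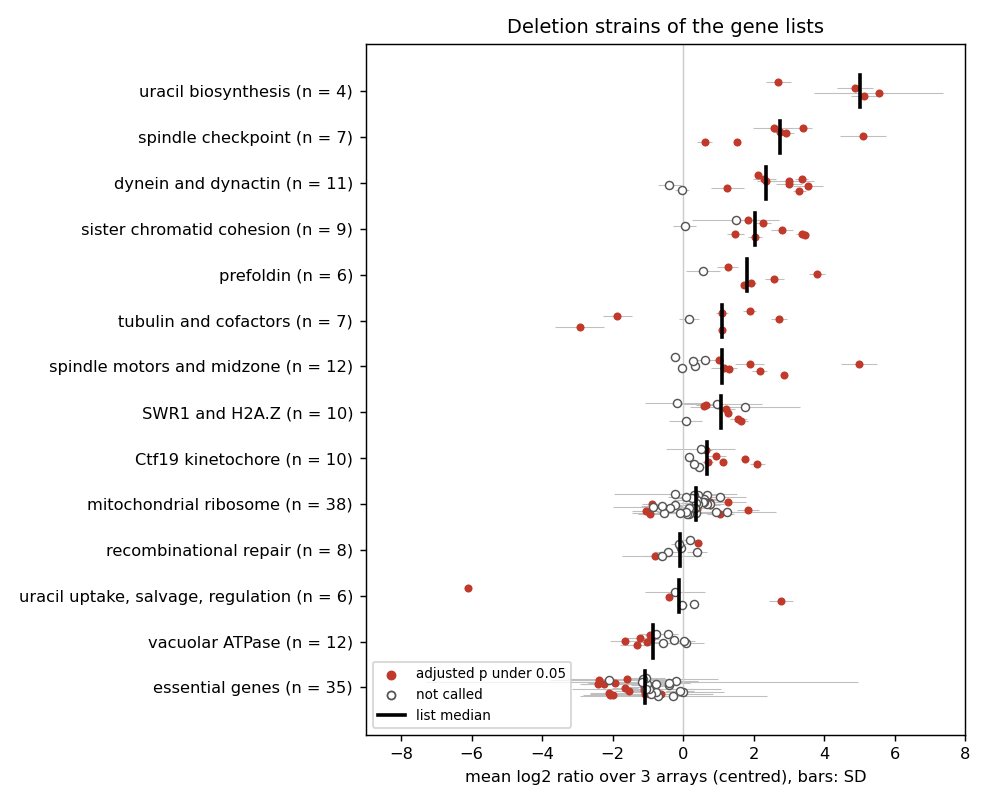
Mean log2 ratio over 3 arrays (horizontal axis, bars SD) of the measured strains of each gene list, filled where called, with the list median as a black bar. Medians run from 5.01 for uracil biosynthesis to -1.07 for the essential genes.

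Strains lacking genes of uracil biosynthesis had large positive ratios. All 4 uracil biosynthesis strains were positive, 3 of them by both tags, with a median of 5.01 and 4 adjusted over the list alone. URA4 stood at 5.54 ± 1.83, URA5 at 5.14 ± 0.37, URA1 at 4.87 ± 0.50 and URA2 at 2.70 ± 0.35. URA4 rested mainly on tag set A (6.73). Tag set B gave 0.11 on 1 array. Camera's adjusted p was 6.9e-04, with an adjusted p = 0.136 with an estimated correlation. In the list of uracil uptake, salvage and regulation, PPR1, the activator of the uracil genes, was positive at 2.79 ± 0.34, by both tags. FUR4 and FCY2 (-0.41 ± 0.08), a purine and cytosine permease, were negative, neither by both tags. For FUR4, tag set A was not measured on all arrays and could not be tested. The other 3 measured members were not called, and the counts adjusted over the list alone were 1 and 2. The median was -0.12 and camera's adjusted p 0.876, with an adjusted p = 0.934 with an estimated correlation.

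Vacuolar ATPase strains, which lack the proton pump of the vacuole, were negative in 6 of 12 cases, 3 of them by both tags, with a median of -0.84, and in 8 adjusted over the list alone. VMA1 stood at -1.65 ± 0.42, VMA6 at -1.32 ± 0.47, VMA5 at -1.23 ± 0.42 and VMA2 at -1.01 ± 0.33 (camera, adjusted p = 0.0037; adjusted p = 0.136 with an estimated correlation). Mitochondrial ribosome strains had a median of 0.37, with 6 positive and 3 negative among 38, or 5 and 3 adjusted over the list alone. MRPS35 was the 1 positive strain called by both tags. MRPS35 stood at 1.85 ± 0.32, MRPL4 at 1.26 ± 0.51 and MRPL10 at 1.05 ± 0.39. The 3 negative strains each had tags of opposite sign, at -3.07 and 0.93 for MRPS5 (-1.07 ± 0.38), -1.89 and 0.13 for MRPL51, and -1.95 and 0.073 for MRPL7. Camera's adjusted p was 0.0089, with an adjusted p = 0.136 with an estimated correlation and 0.0825 in tag set A alone.

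Recombinational repair strains showed no shared shift. RAD54 (0.43 ± 0.09) was positive and MRE11 (-0.80 ± 0.28; tags -1.72 and 0.11) negative among 8, neither by both tags, and 0 were called adjusted over the list alone. The median was -0.10, and camera, which ranked the list slightly upward, gave an adjusted p of 0.996, or an adjusted p = 0.997 with an estimated correlation.

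A list of essential genes was set as a background, since haploids without them do not grow, but whether their tags stem from carry-over was not tested, and ENP1, an essential gene outside the list, stood at 5.63. Of 35 measured strains, 18 were called negative and 0 positive, with a median of -1.07 and an SD across strains of 0.67, and 21 were negative adjusted over the list alone. SPC97 stood at -2.40 ± 0.47, SMC1 at -2.39 ± 0.79, SEC61 at -2.23 ± 0.71 and SRP1 at -2.09 ± 0.55. A single strain was called negative by both tags, and 17 of the 35 had both tags on all arrays. Camera's adjusted p was 2.1e-05, with an adjusted p = 0.136 with an estimated correlation.

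Ratios were next compared with the 5-FOA concentration. In limma's fit of a trend over 0.1, 0.15 and 0.2%, 0 strains were called, the smallest adjusted p was 0.926, and 263 strains had an unadjusted p under 0.05. RPC31, SEN54 and URA4 had the smallest p with a positive slope, at 5.09, 3.88 and 3.65 per 0.1%. RPT4, RFC5 and STU2 had the smallest p with a negative slope, at -6.06, -3.68 and -4.27. For URA4, RPT4 and RFC5 the tags measured differed between arrays. URA4 had 7.23, 5.65 and 7.32 in tag set A in experiments 1, 2 and 3, and a tag set B value (0.11) in experiment 1 alone. RPT4 had tag set B in experiments 1 and 2 and tag set A in experiment 3. RPC31 had tag set A alone, and SEN54 and STU2 had both tags on all arrays. Among the 4293 strains with both tags on all arrays, a set chosen after the values were seen, limma called 0, with 210 at an unadjusted p under 0.05. Each concentration was used in 1 experiment, so that concentration and experiment cannot be told apart.

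Strains of genes near CIN8 on the left arm of chromosome V were examined for linkage. Linked deletions seldom combine in spores if they lie on opposite copies of the chromosome, which was not examined. PRB1 (3.24 ± 0.21), a vacuolar protease gene, and NPR2 (3.56 ± 0.51), a regulator of growth signalling, lie next to CIN8 and were positive. CAN1 (-4.20 ± 0.86, with 2 of 6 values at the lowest ratio), the arginine permease gene, and AVT2 (-1.25 ± 0.18) follow NPR2 and were negative. The 26 strains within 20 ORF numbers had a median of -0.11, at the 47.0th percentile of random sets of that size, and the 16 within 10 numbers a median of -0.36, at the 14.2th percentile. The other 34 strains of the arm had a median of 0.13.

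**Figure D3:**
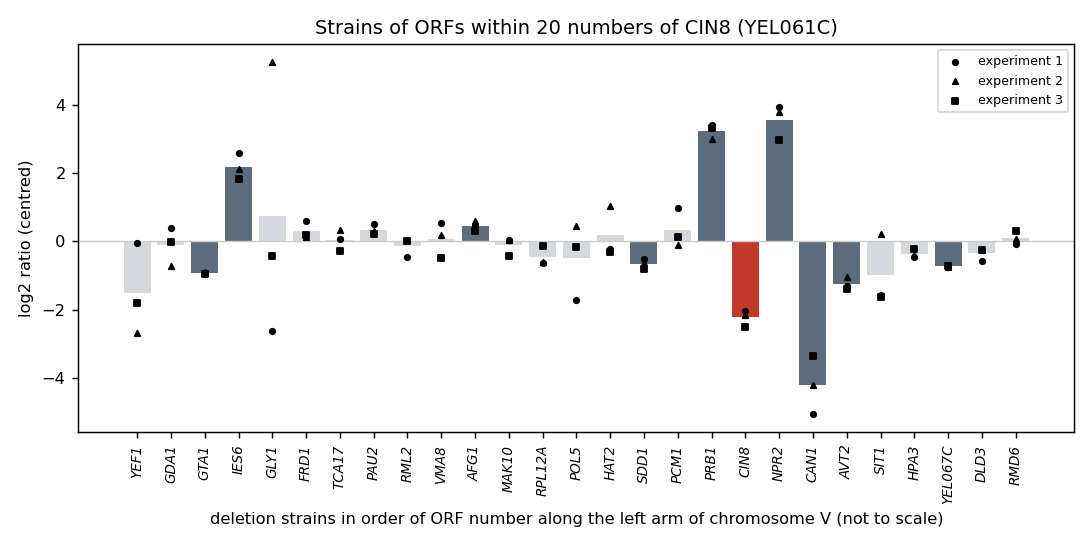
Log2 ratios (vertical axis) of deletion strains within 20 ORF numbers of CIN8, in order of ORF number along the chromosome arm (horizontal axis, not to scale). Bars are means of the 3 experiments, dark where called, CIN8 in red, and symbols are single experiments; PRB1 (3.24) and NPR2 (3.56) stand on both sides of CIN8 (-2.23).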

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

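Among probes with no gene name here, 10 of the 503 pairs with all 6 values (2 tag sets on 3 arrays) had every value at or above 1 (1.99%), which drew attention because these probes were outside the comparisons. The share was 2.96% among all named strains (127 of 4293). The essential genes had 0 of 17, too few to serve as a background (two-sided Fisher's exact p = 1), so that the unnamed pairs were not shown to stand above it. A further 8 unnamed pairs had all 6 values at or below -1. The highest mean of a pair was 4.43. Pearson's r between the tag sets across the 503 pairs was 0.38. No explanation was tested.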

How the results depend on the processing

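The settings for the placeholders, the lowest ratios, the median of spots, the trend with both tags and the further strains outside the naming rule were chosen after seeing the data. Leaving out experiments 1, 2 or 3 gave 0 calls in total, on either side and with the 2-fold limit (0 to 0), and 0 to 2 by both tags. The smallest adjusted p was then 0.0787, 0.0628 and 0.0770, since fewer arrays were tested. The lower of the 2 tag values gave 595 calls (365 positive, 230 negative) and 227 at least 2-fold (139 and 88), of which 557 and 226 were shared with the calls reported. With 5-FOA as a covariate, which takes 1 of the 2 residual degrees of freedom, there were 228 calls, all at least 2-fold (91 and 137). Without centring, which moved array medians by 0.15 to 0.17, 1863 strains were called and the positive share was 32.3% against 48.2%. The other settings kept each count within 1.5 times. With an estimated correlation, which rests on 2 residual degrees of freedom, no list was called, at unchanged medians (0.67 for Ctf19, 2.36 dynein, -1.07 essential, 0.37 mitochondrial ribosome, 1.82 prefoldin, 2.04 cohesion, 2.74 checkpoint, 1.09 motors, 1.09 SWR1, 5.01 uracil biosynthesis, -0.84 vacuolar ATPase). Tag set A alone ended the calls of the mitochondrial ribosome (0.32) and prefoldin (1.81) lists, and tag set B that of SWR1 (0.92). The tubulin list passed with fry (1.10) and without centring (0.93), and the uracil uptake list with fry (-0.12), which does not compare a list with other strains. The median of the uracil uptake list was positive in tag set A (0.080), in tag set B (0.20) and without experiment 3 (0.090). That of the recombinational repair list was positive in tag set B (0.091) and without experiment 2 (0.018). Among the strains named, signs reversed in tag set B for MRPS5 (0.93), GIM4 (-0.36), MRE11 (0.11), BDF1 (-0.43), MRPL51 (0.13), MRPL7 (0.073) and PAC11 (3.28), and in tag set A for BFA1 (-1.31), PAC1 (-0.67), PAC10 (-0.66), BIM1 (-0.18) and DYN1 (1.61). RTF1, of the groups assembled later and not called, also reversed in tag set A (0.40). The lower of the tag values set MRPS5, GIM4, BFA1, PAC1, PAC10, DYN1, PAC11 and MRPL51 to 0, as their tags had opposite signs on every array. DYN1, not called, was 0.12 with the median of spots and -0.12 to 0.075 without 1 experiment; MKK1 ranged over -0.045 to 0.43 and RPT4 over -2.15 to 0.87. Agreement of the tags was 0.62 in called strains, where selection on the mean of the tags can raise it, and 0.43 to 0.45 without 1 experiment. The strains within 10 ORF numbers had a median of -0.36, and the essential genes -1.24 without centring. The strains within 20 ORF numbers had medians of -0.071, -0.24 and -0.083 without experiments 1, 2 and 3. Other causes were not tested. A trend on signal and a filter on low signal were not run, as the files hold no signal. Each ratio already pairs both pools on 1 array, and no further pairing was possible because the series has 1 group.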

Other observations

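Groups outside the fixed lists were assembled after the values were seen, from strains near the ends of the ranking and from textbook partners, so that their counts are not independent evidence. In the NatA acetyltransferase, ARD1 (4.24 ± 0.32) and NAT1 (2.49 ± 0.12), its 2 main subunits, were called positive by both tags, and NAT5 (0.25 ± 0.08) was not called. Among 6 strains of the Lsm ring and messenger RNA decay, 3 were called positive, LSM7 (2.92 ± 0.26), LSM1 (2.65 ± 0.17) and LSM6 (1.18 ± 0.15), all by both tags, while XRN1 was called at -0.51 ± 0.12, not by both. Among 6 protein phosphatase 2A strains 4 were called positive, including PPH21 (2.36 ± 0.25), RRD1 (2.08 ± 0.25) and PPH22 (1.46 ± 0.18), all by both tags, and TPD3 (-0.64 ± 0.23) negative, not by both. Of 4 Paf1 complex strains, CDC73 (3.21 ± 0.16) and LEO1 (1.41) were called positive, while RTF1 (-0.32) and PAF1 (-0.70) were not called. Camera's adjusted p over these 8 lists was 0.0309 for NatA, 0.0647 for Lsm, 0.0746 for the phosphatase and 0.254 for Paf1, and with an estimated correlation each was at least 0.399.

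On the negative side, cell wall integrity strains had a median of -3.06, with 6 of 11 called negative, 4 of them by both tags. TUS1 (-3.44 ± 0.55), RLM1 (-3.45 ± 0.38) and ROM2 (-3.14 ± 1.06) were among them, and BCK1 (-3.34 ± 2.52) was not called. Some values of BCK1 (6 of 36), SLT2 (4 of 26) and SLG1 (1 of 25) of this list were at the lowest ratio, as were some of STE7 and SUR1 of the lists below. SLG1, SLT2 and RLM1 had 11, 10 and 8 empty values. Of the kinase pair of this pathway, MKK1 stood at 0.19 ± 0.47 and MKK2 at 0.28 ± 0.04. Pheromone pathway strains had 5 of 10 negative, STE5 alone by both tags (1 of 5), including STE7 (-4.92 ± 0.82), STE4 (-2.90 ± 0.74) and STE5 (-2.34 ± 0.20). For STE7 and STE4, tag set B was not measured on all arrays and could not be tested. These lists had camera adjusted p-values of 0.0309 and 0.0455, and 0.399 for both with an estimated correlation. In the sphingolipid list, which did not pass (0.728), 3 of 10 strains were negative, SUR1 (-3.83 ± 1.54) and CSG2 (-3.35 ± 0.27) by both tags and SUR2 (-0.51) not, and SCS7 (0.78) and IPT1 (0.73) were positive, neither by both tags. In the arginine list of 6 (0.124) CPA1 and ARG1 (-1.79 ± 0.82) were negative, neither by both tags. For CPA1, tag set B was not measured on all arrays and could not be tested.

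The tests of slow growth, of dye bias and of a common dye shift on both sides, of the side of loss, of the cassette, of linkage to neighbours and of cell wall strains were chosen after the results were seen; those of chance, low signal and linkage to CAN1 were written before, although the value of CAN1 itself had been seen.

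The first pattern is the positive side, where a dye bias of single tags would not carry over to the other tag, but of 315 strains called by tag set A at 2-fold or more, 270 were positive in tag set B (85.7%, exact 95% interval 81.4 to 89.4), against 51.0% of all strains. A dye shift common to all strains of an array was removed by the centring before strains were called. It also cancels from the difference in medians between these strains and all strains in tag set B. That difference (1.14 without centring, SD over the arrays 0.02) is thus no separate test of it. A test of slow growth was split between 2 lists. The vacuolar ATPase list lay at -0.84 (camera, adjusted p = 0.0037, and 0.136 with an estimated correlation), with 6 negative and 0 positive. The mitochondrial ribosome list passed on the positive side at 0.37 (0.0089, and 0.136). The essential genes, set as a background, lay at -1.07, so that vacuolar ATPase strains near it do not decide the question. Slow growth stays open as a cause of part or all of this side. The 4 sign patterns of 3 arrays are too few for a share under 0.05; the real pattern alone (1 of 4) gave 1748 calls and the highest other 0. A dye effect that varies with signal and a general effect of the URA3 selection stay open, and loss of strains that need CIN8 may account for the spindle lists as a hypothesis, for which no array with another query was analysed here.

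The second pattern is the negative side, where 30.5% of the called strains had at least 1 empty probe value (276 of 906), against 24.3% of those not called (839 of 3456) and 4.28% of those called positive, with exact intervals that do not overlap. Among strains measured by both tags, which seldom have empty values, the share was 10.6% in those called negative by both tags (26 of 245) and 5.29% in those not called (146 of 2762), again without overlap, so that low tag signal may account for part of this side. The essential genes, set as a background, had a median of -1.07. Of them 18 of 35 were called negative and 0 positive, against 906 negative among the 5204 strains tested. Strains with little signal in both pools may thus be called negative without a change between the pools, which was not tested. Dye bias of single tags as the whole cause is argued against by 83.6% of strains keeping their sign in the other tag (290 of 347), although the share was 75.6% when tag set B made the selection. A common dye shift was likewise removed by the centring before the calls. It cancels from the difference in medians between these 347 strains, chosen in tag set A, and all strains in tag set B. That difference (-0.85 without centring, SD over the arrays 0.05) is thus no separate test of it. Loss of cell wall mutants on 5-FOA stays open at a median of -3.06, since some members were chosen from their values.

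The third pattern is the CIN8 locus, and with it the direction of the ratio. That negative values mark loss from the double-mutant pool is argued against by the uracil biosynthesis strains, whose lowest value was 2.70. Positive values are thus the likely side of such loss, as a hypothesis that takes these strains to need uracil. CIN8 itself then lies on the wrong side, and tags carried on the query cassette could give this; its tags differed by 0.14, which decides nothing. Linkage to a selection marker at CAN1 cannot be told apart from chance at a median of -0.36 within 10 ORF numbers, with a spread of random sets of 0.22. That window was centred on CIN8 and held PRB1 and NPR2, so that it is a weak test of linkage to CAN1. The measured strains from CAN1 (-4.20) outward to DLD3 (-0.35) all had means below 0, and RMD6, beyond them, stood at 0.10. CAN1, AVT2 and YEL067C were called, while SIT1, HPA3 and DLD3 were not. This stretch was chosen after the values were seen. Meiotic linkage as the reason for PRB1 and NPR2 was examined in the 14 strains 2 to 10 ORF numbers away. Their median of -0.41 does not decide it, since linkage to CAN1 could act on the same strains. Which copy of the chromosome received the cassette was also not examined. An overlap of the cassette's flanks with PRB1 and NPR2 was not tested.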
